A study of Mus musculus with 2 samples.

How the data were processed

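RNA of mouse bone marrow-derived dendritic cells was measured on 2 one-colour Agilent expression arrays. 1 array was hybridised with RNA labelled as coming from EGR1-deficient cells and 1 with RNA labelled as wild type (WT). Per the labels' protocols, femoral marrow cells were grown with 10 ng/ml GM-CSF, a cytokine that turns marrow precursors into dendritic-like and macrophage-like cells, and were harvested on day 6. Total RNA was converted to cRNA carrying the Cy3 dye, per the labels. Both arrays were on the same slide and were read in the same scan, per the file headers, so slide and scan do not separate the groups.

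The values used are spot intensities on a linear scale, as the authors deposited them in the scanner output. Per the file headers, these were made with Agilent Feature Extraction 12.1.0.3, whereas the submitters' processing notes name version 11.5.1.1. The processed intensity is the scanner program's final signal, and per the file headers background subtraction and spatial and multiplicative detrending were among its steps. The authors also deposited a series table of intensities. Set against the scanner values spot by spot, it equals the processed intensity multiplied by 1 constant per array, 6.18 for the array labelled EGR1-deficient and 5.97 for the WT array, with no centring. The origin of these constants is not given in the sources used here. That table lists 29296 spots, all of them well above background on both arrays, with column medians of 1205 for the array labelled EGR1-deficient and 1114 for WT. Another 2498 spots well above background on both arrays are not listed in it, and it served only as an alternative source.

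Each array held 62976 spots, of which 59305 were not controls, covering 56605 probes. On the array labelled EGR1-deficient, 35492 of these spots (59.8%) were well above background by the scanner program's own call, against 32736 (55.2%) on the WT array. The spots called on the array labelled EGR1-deficient alone numbered 3698, and those called on the WT array alone 942. No spot was saturated. The average net signal of the negative controls, per the file headers, was 41.3 on the array labelled EGR1-deficient, which the header marks as outside its accepted range, and 38.7 on the WT array. Outlier spots marked by the scanner program, 77 and 79, were left out. Array number limits the precision: there is 1 array per group, so no p-value was computed and no difference has a replicate check.

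Log2 processed intensity minus the array's 75th percentile over non-control spots (191.6 and 183.0) was taken as the expression value, and differences are given as the array labelled EGR1-deficient minus WT. Repeated spots of a probe were averaged on the log2 scale. Probes were named through their transcript accession in a RefSeq gene table of assembly GRCm38.p6, used for names and chromosomes only because the array files name build mm9. This named 34566 probes as 23787 genes and left 22039 probes unnamed here. A gene was represented by its probe of highest mean signal, and of its other probes above background on both arrays the furthest is cited where it lies over 0.17 log2 units away, the median SD between 2 probes of a gene. Genes with that probe well above background on both arrays entered the counts of genes 2-fold or more apart. For a gene well above background on 1 array only, an at-least fold was computed against the higher of the lowest well-above-background signal on the dim array (13.3 on the array labelled EGR1-deficient, 16.3 on WT) and the probe's own signal there. No fold is given where this bound came to 1.

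Before the data were examined, 31 gene lists with 604 different genes were fixed, of which 594 had a probe. The median difference of each list with at least 5 members above background on either array was placed among 10000 random lists of the same size, matched on mean signal in 20 bins. A median below the 2.5th or above the 97.5th percentile was called lower or higher. Random lists ignore that genes of a pathway vary together, so the percentile describes these 2 arrays and does not test genotype. Genes to be named were also fixed by rule: Egr1, the 12 highest and 12 lowest differences among genes with a full symbol, a mean signal at or above the 25th percentile and all probes of the same sign, the 4 largest at-least folds per direction, and up to 4 members of each list with the largest difference. Members of the EGR family and Y-linked lists that were not above background are named too, as checks of the labels. Any other gene outside this rule is marked in the text as chosen after its values were seen.

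Technical error was taken from 300 probes printed 10 times and from genes with 2 probes. The counting and list steps were tested on simulated data for the comparison of the array labelled EGR1-deficient with WT, over 13725 genes with noise of 0.17 log2 units. They returned 100 of 100 genes changed 3-fold, 0 of 100 genes changed 1.5-fold and 0 of 13505 unchanged genes at the 2-fold threshold. This noise was the same at all signal strengths and below the root mean square SD of 0.31 between 2 probes of a gene. With it an unchanged gene could hardly reach 2-fold, so the test checks the steps only. It does not give the number of false calls among genes counted on the real arrays. Of 200 simulated null lists, 10 fell outside the central 95% of random lists.

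Alternatives fixed in advance were quantile normalization, cyclic loess normalization, normexp background correction (offset 50) followed by quantile normalization, equal medians of detected probes, the authors' series table, no filter on dim probes, a stricter filter on mean signal, the mean of a gene's probes, and thresholds of 1.5-fold and 3-fold. The spots of the series table with the percentile scaling were added after seeing the data. The normexp step had been planned on mean spot signals. The median spot signal was used in its place, since the scanner output used here has no mean column. Tools were R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.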

Results

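Bone marrow-derived dendritic cells (BMDCs) are antigen-presenting cells grown from marrow precursors with GM-CSF. The series belongs to a study of lactate and inflammation in dendritic cells, and this part compared BMDCs of C57BL/6J mice labelled EGR1-deficient with BMDCs labelled wild type. EGR1 is a zinc-finger transcription factor of the immediate early class, made within minutes of many stimuli. 1 array was read per label. Of 59305 spots, 59.8% were well above background on the array labelled EGR1-deficient and 55.2% on the WT array. There were no replicates, so every value is a single reading. The only errors are technical: repeated spots of 1 probe had a median SD of 0.06 log2 units on each array, which gives 0.08 for a difference, and 2 probes of the same gene differed with a median SD of 0.17 and a root mean square SD of 0.31.

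The targeted gene did not bear out the labels. Egr1, on chromosome 18, had a signal of 1212 on the array labelled EGR1-deficient and 379.7 on the WT array, a difference of 1.61 log2 units or 3.05-fold. Egr1 was measured by 1 probe, and where that probe lies in the gene relative to the targeted part is not given in the sources used here. A probe outside a deleted part tests nothing about the label. The direction of every comparison therefore rests on the labels as given. Egr1 does not bear them out, and with the probe's position unknown it does not refute them.

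The other EGR family members gave smaller differences or lay near background. Egr2, a related factor that shares EGR1's DNA motif, was lower on the array labelled EGR1-deficient, at 828 against 1245 (difference −0.65). Egr3 differed by −0.34 in the probe above background on both arrays, and another of its probes read 10.6 against 21.5, above background on the WT array only. Egr4 was well above background only on the array labelled EGR1-deficient, where it was at least 1.23-fold higher. Nab2, which encodes a co-repressor that binds EGR proteins, differed by 0.02 and −0.15 in its 2 probes, and Wt1 was not well above background on either array. With 4 measured members the family list was below the minimum of 5. Among 20 measured genes often cited as EGR1 targets, the median difference was −0.14, at percentile 11.8 of matched random lists. The largest differences in that list were those of Ptgs2, which encodes the inducible cyclooxygenase (−0.67), the cell cycle inhibitor Cdkn1a (−0.48, with another probe at 0.09), the urokinase gene Plau (−0.47) and Pdgfa (−0.38, another probe −0.80).

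Both samples are labelled male. Xist, the X-inactivation RNA normally made in female cells, had a signal of 4559 on the array labelled EGR1-deficient and 3425 on the WT array. The Y-linked genes Ddx3y, Kdm5d (3 probes) and Uty were not well above background on either array. For Eif2s3y, 1 of its probes read 27.1 and 25.6, and the other was not well above background. Apart from that 1 dim probe, these readings go against the male label of both arrays. The reason was not tested.

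**Figure D1:**
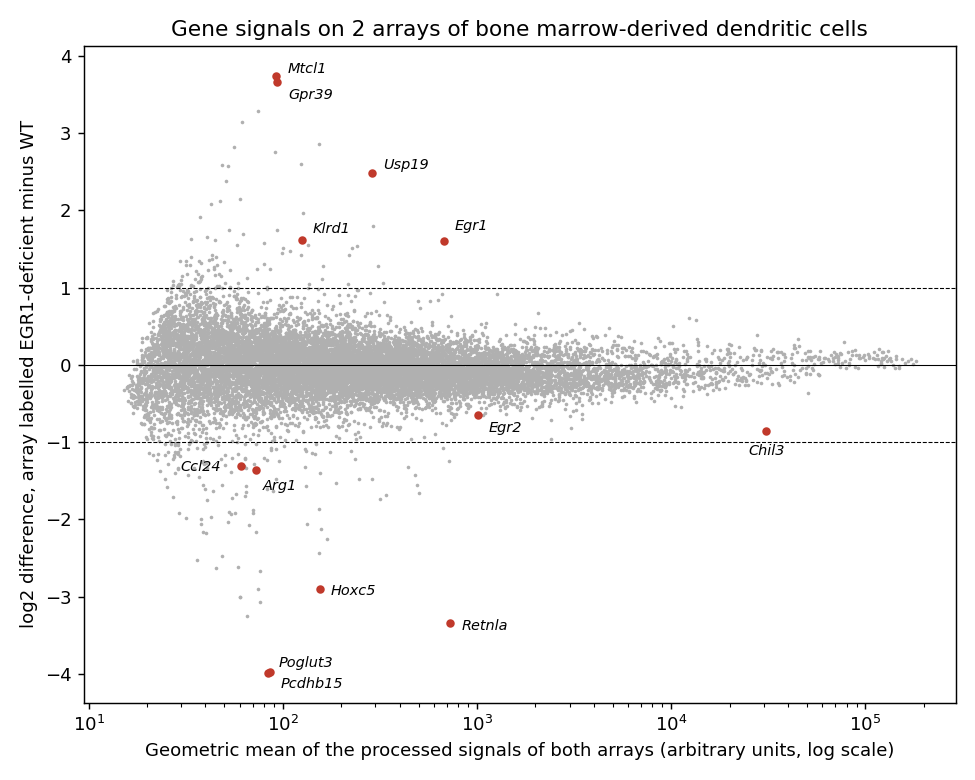
Difference between the 2 arrays (log2, array labelled EGR1-deficient minus WT) against the geometric mean of their processed signals (arbitrary units, log scale) for 13725 genes above background on both arrays, with dashed lines at 2-fold. Egr1 lies at 1.61, Retnla at −3.34 and Chil3 at −0.86.

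The 2 arrays were close over most genes, with a small number far apart. Retnla, which encodes the secreted protein RELM-alpha of alternatively activated macrophages, read 235 on the array labelled EGR1-deficient and 2269 on the WT array, 10.1-fold lower. The neural adhesion genes Pcdhb15 (−3.98) and Ctnnd2 (−2.66), the homeobox gene Hoxc5 (−2.91), the RNA helicase gene Ddx51 (−2.44) and the glucosyltransferase gene Poglut3 (−3.99) were also lower there. On the higher side of the array labelled EGR1-deficient stood the microtubule-binding factor Mtcl1 (3.74), the zinc-sensing receptor Gpr39 (3.66), the tyrosine kinase Fer (3.28), the Ral GTPase regulator Ralgapa2 (2.86) and Klrd1, which encodes the CD94 receptor of natural killer cells (1.62). Several of these differences rest on a dim reading. Mtcl1, Gpr39 and Fer read 24.8, 25.8 and 23.3 on the WT array, where the lowest signal well above background was 16.3. Poglut3 and Pcdhb15 read 21.6 and 22.1 on the array labelled EGR1-deficient, where it was 13.3. Gpr39, Fer, Ralgapa2 and Ctnnd2 have further probes that were not above background on both arrays.

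Across 13725 genes above background on both arrays, the signals correlated with r = 0.988, a value across genes, which are not independent replicates. Of these genes, 92.3% lay within 1.5-fold. At 2-fold or more, 97 genes were higher on the array labelled EGR1-deficient and 138 were lower. It was 18 against 31 after normexp, and 1280 against 971, with more genes higher than lower, without a filter on dim probes. The split was 77 against 174 after quantile normalization and 73 against 184 after loess. With the authors' series table, which has another scale and fewer spots, it was 103 against 68. The spots of that table on the percentile scale, an alternative chosen after seeing the data, gave 67 against 88. The other highest genes were Tigd5 (2.60), the deubiquitinase gene Usp19 (2.48), the acyl-CoA thioesterase gene Acot1 (1.97), the ubiquitin ligase gene Marchf9 (1.80), the phosphodiesterase gene Pde11a (1.75) and the lipase gene Cel (1.58). The other lowest were Rbm41 (−3.07), Tdpoz1 (−2.90), Abi3bp (−2.25), Lrrc40 (−2.12), the pentose phosphate enzyme gene Rpe (−2.06) and the mitochondrial carrier gene Slc25a26 (−1.86). Most of these genes rest on 1 probe above background on both arrays. Rbm41 and Tdpoz1 were also dim on the array labelled EGR1-deficient, at 27.1 and 28.0. For Usp19, Pde11a, Rpe and Slc25a26 another probe differed by only 0.13, 0.24, −0.19 and −0.15.

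A further 1278 genes were above background only on the array labelled EGR1-deficient and 371 only on the WT array, of which 183 and 192 were at least 2-fold apart. Klhl23 was at least 48.8-fold higher on the array labelled EGR1-deficient, Tmc5 35.7-fold, Cyp2d13 27.8-fold and C1qtnf1 23.7-fold. The lens crystallin gene Crygn was at least 64.9-fold lower there, the ephrin receptor gene Epha8 24.7-fold, the pseudogene Olfr367-ps 20.1-fold and Slc5a4a 19.9-fold. All of these genes but Tmc5 and C1qtnf1 were measured by 1 probe, and none had a probe above background on both arrays. The bound allows for the dim array only, so the bright reading of a single probe is unchecked.

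Macrophage, chemokine and interferon-stimulated genes were lower as groups on the array labelled EGR1-deficient, in the direction drawn from labels that Egr1 does not bear out. Over the 13725 genes above background on both arrays the median difference was −0.05, so a count below 0 does not by itself set a list apart. Of 26 measured macrophage markers, 25 were below 0, with a median difference of −0.37. Besides Retnla these included Arg1, which encodes arginase (46.3 against 113, −1.36), the chitinase-like gene Chil3 (23407 against 40560, −0.86) and the complement gene C1qc (−0.64). Of 20 chemokines, 17 were below 0 and the median was −0.39. The eosinophil attractant Ccl24 differed by −1.30, the monocyte attractant Ccl12 by −0.90 and the neutrophil attractant Cxcl1 by −0.87, and Ccl7 was above background only on the WT array, at least 1.68-fold lower. Of 28 interferon-stimulated genes, 26 were below 0 with a median of −0.27, led by the GTPase gene Gbp3 (−0.65), the DNA sensor family member Ifi205 (−0.46), Rtp4 (−0.43) and Ifi44 (−0.40).

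The list of basophil, mast cell and eosinophil markers, called the granule-cell list here, was lower in the same way. It holds no neutrophil list: granulocyte markers formed a separate list, which stayed inside the random range. Among 17 measured genes of basophils, mast cells and eosinophils, 15 were below 0 and the median was −0.32. The eosinophil ribonuclease gene Ear6 differed by −0.94 (another probe −0.15), the major basic protein gene Prg2 by −0.69, the eosinophil peroxidase gene Epx by −0.64 and the basophil protease gene Mcpt8 by −0.63. The medians of the macrophage and chemokine lists lay at percentile 0 of matched random lists, and those of the interferon-stimulated and granule-cell lists at percentile 0.01. Their size varied over the settings fixed in advance. It ran from −0.37 to −0.23 for macrophage markers and from −0.40 to −0.19 for chemokines. For interferon-stimulated genes it ran from −0.27 to −0.15, and for the granule-cell list from −0.45 to −0.20.

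Smaller differences were seen in 2 further lists. Genes of glycolysis and lactate transport had a median of −0.20 (percentile 0.63), with 25 of 28 below 0, among them the monocarboxylate transporter Slc16a1 (−0.67), the enolase Eno2 (−0.61), the pyruvate dehydrogenase subunit Pdha1 (−0.60) and Pgam1 (−0.47). MHC class I presentation genes had a median of −0.19 (percentile 2.34), with 15 of 18 below 0, including the immunoproteasome subunit Psmb8 (−0.49), the transactivator Nlrc5 (−0.48, another probe 0.18), Calr (−0.41) and Pdia3 (−0.29). After loess normalization the medians of both lists shrank to −0.07, at percentiles 3.60 and 3.06, inside the random range, whereas after quantile normalization they were −0.12 and −0.11 and stayed below it. MHC class I was also inside the range without the filter on dim probes (percentile 2.9) and with the mean of a gene's probes (percentile 9.34), and glycolysis with the stricter filter (percentile 3.22). For comparison, 18 reference genes had a median of −0.15 (percentile 10.4), led by Gusb (−0.42, another probe −0.23) and B2m (−0.28). Of these reference genes 15 were also below 0, the same count as for MHC class I.

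Stromal and osteoclast markers formed the list that was higher on the array labelled EGR1-deficient, with a median of 0.64 over 16 genes (percentile 99.98). Of these genes 12 were above 0 and 4 below. Calcr, the calcitonin receptor of osteoclasts, was above background on that array alone and at least 12.8-fold higher. The matrix gene Dcn was at least 1.83-fold higher, and Col1a2 (1.05) and Pdgfrb (0.99) were above background on both arrays. Other osteoclast genes, chosen after their values were seen, went both ways. The phosphatase gene Acp5 read 884 against 1318 (−0.64), the proton pump subunit gene Atp6v0d2 531 against 701 (−0.47, another probe −0.09) and the fusion gene Dcstamp 358 against 447 (−0.39, another probe −0.84). Oscar read 1229 against 989 (0.25), and Ocstamp was at least 1.64-fold higher on the array labelled EGR1-deficient. Because 7 of the 16 genes were above background on 1 array only, the median with those genes at their bounds was 0.40, and over genes above background on both it was 0.25. With the authors' series table the median was −0.09 (percentile 9.5). That table lists only spots above background on both arrays, so these 7 genes, all higher on the array labelled EGR1-deficient, could not enter.

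**Figure D2:**
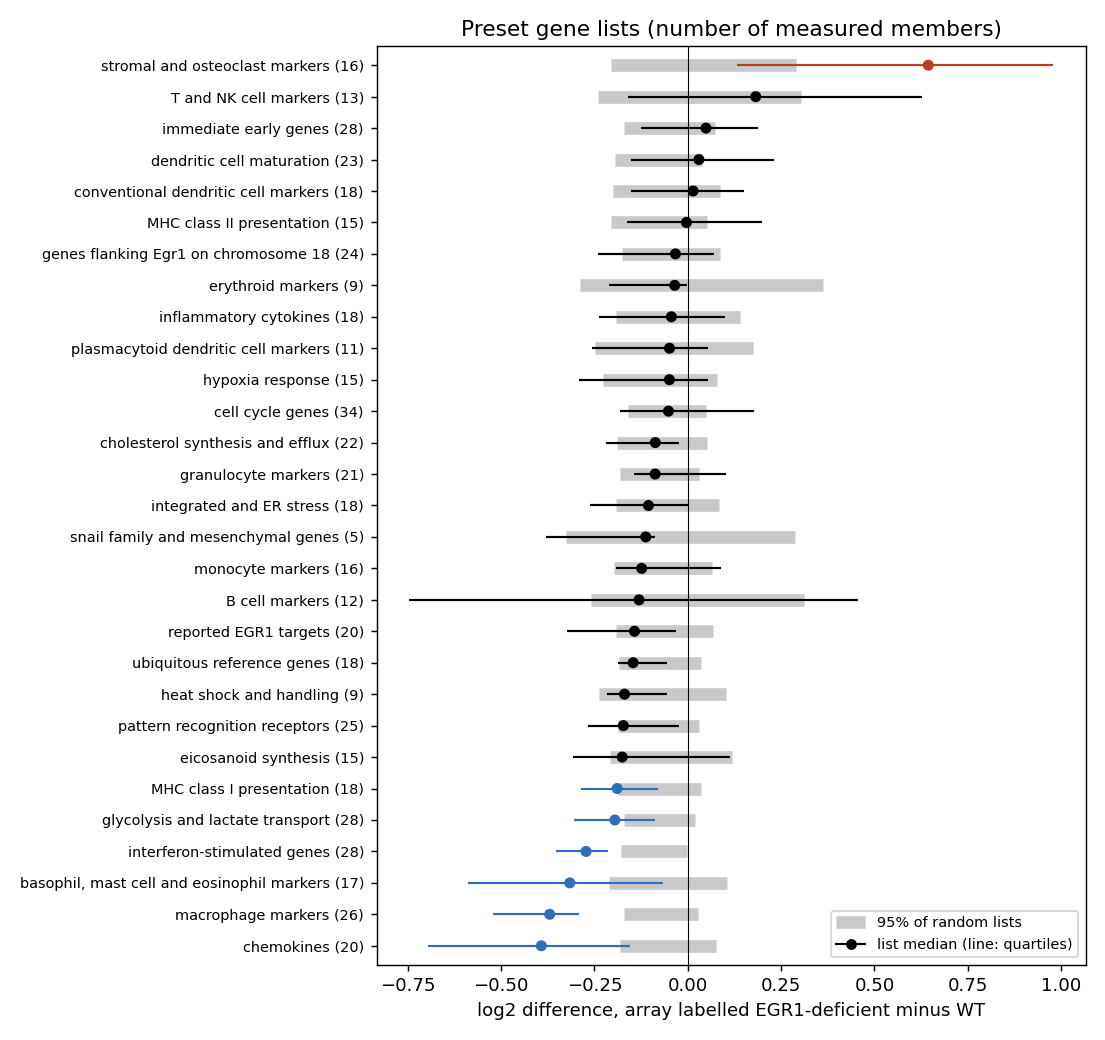
Median log2 difference (array labelled EGR1-deficient minus WT) of 29 preset gene lists, with lines for the quartiles of their members and grey bars for the central 95% of 10000 random lists matched on signal; blue lists lie below and the red list above that range. Chemokines lie lowest at −0.39, a list of stromal and osteoclast markers highest at 0.64. This median was −0.09 with the authors' series table, which leaves out the 7 members above background on 1 array only.

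Dendritic cell identity and maturation genes did not stand apart. Conventional dendritic cell markers had a median of 0.01 (percentile 84.6), with the endocytic receptor Ly75 at 0.53, the growth factor receptor Flt3 at 0.50 and Kmo at −0.40 (another probe 0.15). Maturation genes had a median of 0.03 (percentile 96.7), with the costimulatory genes Tnfsf4 at 0.74 and Cd40 at 0.43 and Cd86 at −0.41. This list passed the upper limit under 4 of the alternatives fixed in advance, with a median of 0.11 after quantile normalization, 0.12 after loess, 0.09 after normexp and 0.14 with the authors' series table. MHC class II genes had a median of −0.0036 (percentile 89.4), where H2-Ob, which limits peptide loading, read 0.77 and H2-Eb2 0.54 (another probe 0.23). Inflammatory cytokines had a median of −0.04 (percentile 42.8). In that list Il1a was at least 2.09-fold and Ifnb1 at least 1.63-fold lower on the array labelled EGR1-deficient, Il10 was at least 1.30-fold higher, and Lif had no bound above 1.

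Immediate early genes, the class to which Egr1 belongs, had a median of 0.05 (percentile 93.9), and passed the upper limit with the stricter filter (percentile 98.2). Maff was at 0.86 and Atf3 at −0.58, while Fosl1 was at least 1.40-fold higher and Dusp4 at least 1.61-fold lower on the array labelled EGR1-deficient. Pattern recognition receptors had a median of −0.17 (percentile 4.32), with the RNA sensor Tlr7 at −0.93 and another of its probes at 0.13. This list passed the lower limit after loess (median −0.12, percentile 2.44) and with the mean of a gene's probes (median −0.17, percentile 2.19). Eicosanoid synthesis genes had a median of −0.18 (percentile 5.58). Cholesterol synthesis and efflux genes had a median of −0.09 (percentile 42.2), in which the sterol exporter Abca1 read −0.90 (another probe −0.44) and its regulator Nr1h3, the liver X receptor alpha gene, −0.74. Hypoxia response genes (median −0.05, percentile 68.2) were led by Ankrd37 at −0.66 and P4ha1 at −0.66 (another probe −0.28).

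**Figure D3:**
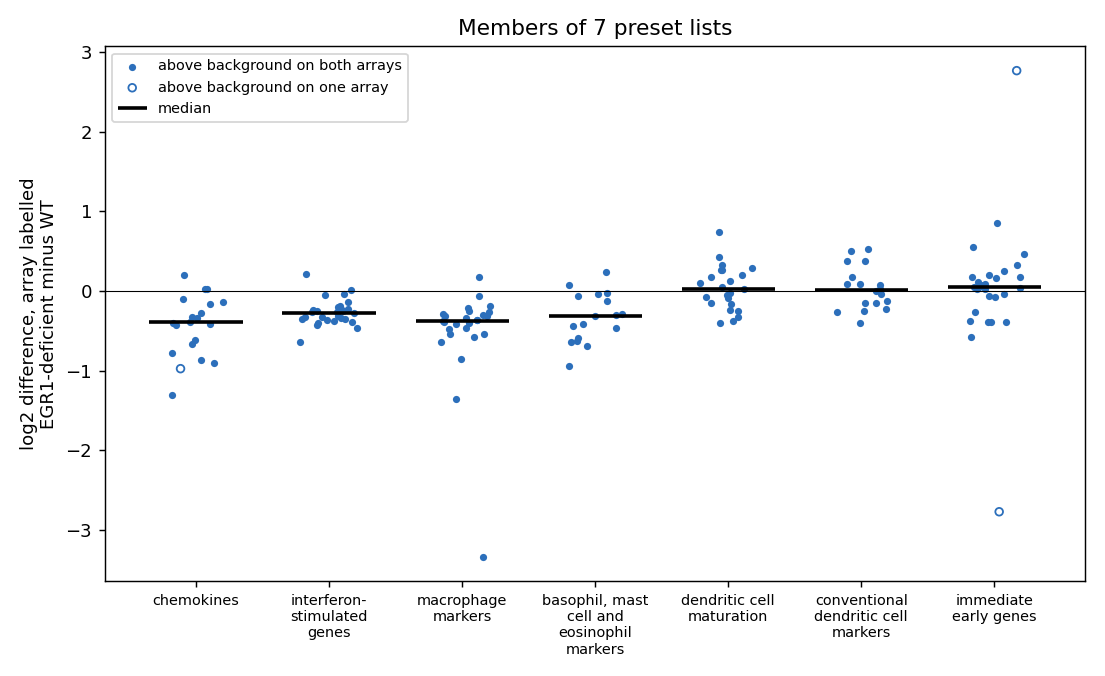
Log2 difference (array labelled EGR1-deficient minus WT) of each measured member of 7 preset lists, with a bar at the list median; open circles are genes above background on 1 array only, whose size is not measured. Macrophage markers have a median of −0.37 with Retnla at −3.34, and conventional dendritic cell markers a median of 0.01.

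Marker lists of the other marrow cells lay inside the random range, except B cell markers under 1 alternative. Monocyte markers had a median of −0.12 (percentile 21.4), with Fn1 at −0.54 (another probe −0.32) and Cx3cr1 at 0.32 (another probe 0.86). Granulocyte markers had a median of −0.09 (percentile 46.9), with the antimicrobial peptide gene Camp at 0.45. B cell markers had a median of −0.13 (percentile 14.5), with Ebf1 at −1.15 and Cd79b at −1.09. Over the 9 of 12 above background on both arrays the median was −0.58, and with the mean of a gene's probes the median was −0.28 (percentile 1.43), below the range. T and NK cell markers had a median of 0.18 (percentile 88.1), with Cd3g at least 2.29-fold higher on the array labelled EGR1-deficient, Klrd1 at 1.62 and Il2rb at −1.06. Plasmacytoid dendritic cell markers (−0.05, percentile 50.5) and erythroid markers (−0.04, percentile 32.8) lay near the middle.

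Cell cycle genes had a median of −0.05 (percentile 53.3), although the ribonucleotide reductase gene Rrm1 (−1.21) and the mitotic kinesin gene Kif11 (−1.11) were more than 2-fold lower on the array labelled EGR1-deficient. Integrated and ER stress genes had a median of −0.11 (percentile 24.6), with the pseudokinase gene Trib3 at 1.13. Heat shock genes had a median of −0.17 (percentile 11.8), and 5 measured genes of the snail family list −0.11 (percentile 31.9). The 24 measured neighbours of Egr1 on chromosome 18 had a median of −0.03 (percentile 59.0). In all, 29 of the 31 lists could be read, 6 were called lower and 1 higher. If genes were drawn at random, 1.45 would lie outside the central 95%. Genes of a list vary together, so 1.45 is not the number that 2 cultures of the same genotype would give. The Y-linked and Xist list had 2 measured members and was not read.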

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

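The tests of explanations in this part, and the genes Dtwd2 and Mc2r, were chosen after the result was seen. Probes without a gene name here were left out of every comparison. Of 9673 such probes above background on both arrays, 120 were 2-fold or more higher on the array labelled EGR1-deficient and 103 were lower, a difference in data that the gene counts do not cover. Probe A_66_P121828 read 1290 on the array labelled EGR1-deficient and 36.9 on the WT array (5.06), and A_66_P118095 read 451 and 31.0 (3.80). Probe A_52_P779430 read 19.7 and 679 (−5.18), and A_30_P01025408 read 19.1 and 334 (−4.20).

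The Egr1 signal was higher on the array labelled EGR1-deficient. A probe lying in a stretch of the transcript that is missing in either culture is argued against, since the weaker Egr1 signal stood 4.54 log2 units above the lowest signal well above background on its array. A stronger general immediate early response is also argued against as the whole cause: that list had a median of 0.0487, and its upper quartile of 0.19 is far below 1.61. An exchange of the 2 labels may account for the direction, but it stays open, because Egr1 was well above background on both arrays (2 of 2) and neither array lacked it. A targeted allele that still makes RNA under the probe also stays open and was not tested.

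Genes 2-fold or more apart by their brightest probe may reflect changes of RNA or features of single probes. In the 30 such genes with another probe above background on both arrays, the other probes had a median difference of 0.25 in the same direction. Their quartiles were −0.27 and 0.65, against a median of 1.29 for the first probe. The other probe was 2-fold or more apart the same way in 3 genes and 1.5-fold or more in 8. In 12 genes it went the opposite way. Most of these 2-fold differences were thus not repeated by another probe. RNA change and single-probe effects cannot be told apart for these genes as a set. Light from a brighter spot close by is argued against: the brightest spot within 2 rows and columns differed by −0.0391 log2 units from that around genes within 1.5-fold, with a bootstrap interval of −0.31 to 0.30. DNA of another strain around the targeted locus on chromosome 18 is argued against as the main source, since that chromosome held 4 of the 235 genes, 1.205% of its 332 genes (exact 95% interval 0.33 to 3.06) against 1.72% of the others. For those 4 genes, Egr1, Pcdhb15 (−3.98), Dtwd2 (−1.74) and Mc2r (1.14), it stays open, as does strain DNA elsewhere.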

How the results depend on the processing

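All alternatives in this part were fixed before the data were examined, except that normexp ran on median in place of mean spot signals, and except 1 chosen after seeing the data, the spots of the series table on the percentile scale. No paired analysis was possible because each group has 1 array, so the groups share fewer than 2 replicate numbers. Against 97 genes 2-fold or more higher and 138 lower on the array labelled EGR1-deficient, normexp gave 18 and 31, no filter on dim probes 1280 and 971, the stricter filter 9 and 13, a 1.5-fold threshold 482 and 573, a 3-fold threshold 26 and 47, and 68 were lower with the authors' series values. The spots of that table on the percentile scale gave 88 lower. The filters and thresholds act by construction, since they admit fewer or more genes. For the others the cause was not tested. Genes on 1 array only and at least 2-fold apart went from 183 and 192 to 38 and 49 with normexp, and these counts could not be made with the series table, without a filter or with the stricter filter. The Egr1 difference of 1.61 was 1.72 with the series table and stayed positive under all 8 settings fixed in advance. Lists called lower numbered 5 to 7, and those called higher 2 after quantile, loess and normexp normalization against 1. The chemokine, interferon-stimulated, macrophage and granule-cell lists were lower under all 8 settings fixed in advance, MHC class I under 5, glycolysis under 6 and stromal markers under 6 of 8. The stromal median reversed to −0.0936 with the series table and to −0.209 with its spots on the percentile scale. The choice of spots alone thus reversed it, through the members that were left out. Among those left out were the 7 above background only on the array labelled EGR1-deficient, all of them higher there. This list had too few members under the stricter filter. The series table moved the median of all genes from −0.05 to 0.06. Of the 23 highest and lowest genes besides Egr1, 20 stayed 2-fold apart with normexp and 17 of 18 with the series table. With the mean of a gene's probes 20 did, and under all 3 settings the direction stayed the same. That mean could change only genes with another probe above background on both arrays, here Usp19, Pde11a, Rpe and Slc25a26. The genes it took below 2-fold were thus among these, and for the others it was no check. Over all named genes besides Egr1 the size was less stable, counting shifts above the technical SD of 0.08. It moved for 147 genes with normexp (19 did not), 72 with loess (94 did not) and 67 with quantile normalization (99 did not). With the series table, whose scale shifts every gene, it moved for 119. Signal over background limits dim genes: the array labelled EGR1-deficient had 1278 genes that the WT array did not lift above background, against 371 the other way.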

Other observations

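The tests of explanations in this part, though not the normalizations they use, were chosen after the result was seen, as were the genes of this paragraph and the next one. The genes Rnase2a, Ear1, Ear2 and Ear10 encode eosinophil-associated ribonucleases, and each was lower on the array labelled EGR1-deficient. Rnase2a read 289 against 875 (−1.66), Ear1 292 against 822 (−1.56), Ear2 176 against 468 (−1.47) and Ear10 478 against 1083 (−1.25). Ear6 of the same family differed by −0.94 in its brightest probe and −0.15 in the other, and no family list was tested. Their probe sequences were not compared. Since 1 transcript may light several probes of related genes, they do not count as separate observations. Prg3, a granule protein gene outside that family, was also lower in both of its probes (−1.33 and −0.95). Under the 6 alternatives fixed in advance that measured these genes, Rnase2a, Ear1, Ear2, Ear10 and Prg3 kept this direction.

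On the higher side of the array labelled EGR1-deficient stood Ltb, which encodes lymphotoxin beta, at 167 against 58.5 (1.45). Klra2, a lectin-like receptor gene of the natural killer complex on chromosome 6 like Klrd1, read 1776 against 895 (0.92, another probe 0.73). The inflammasome sensor gene Nlrp1b had a difference of 1.51 in its brightest probe and 0.38 in another. Batf2, an interferon-responsive transcription factor gene, was lower, at 97.8 against 206 (−1.14).

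The lower medians of 6 lists may come partly from a bias between the arrays that follows signal strength. After loess normalization, which removes such a bias, 4 of the 4 chemokine, interferon-stimulated, macrophage and granule-cell lists were still below the random lists. Their medians were −0.27, −0.18, −0.24 and −0.22, against −0.39, −0.27, −0.37 and −0.32 before, so their size depended on the normalization. The random lists were matched on signal and share such a bias, so a place below them could not test it. For the MHC class I and glycolysis lists 0 remained after loess, but both stayed below after quantile normalization, at percentiles 0.43 and 0.30. For the same reason these calls do not decide on such a bias. A smaller share of macrophages as a whole is argued against for Retnla, since the other macrophage markers without Arg1 had a median of −0.37 and a lowest value of −0.86 against −3.34. Arg1, left out of that comparison, was at −1.36. These values cannot speak to a smaller share of a macrophage subset that makes Retnla, which was not tested. For the 24 markers without Retnla and Arg1 a smaller share stays open, because 23 were below 0, and lower RNA per cell cannot be told apart from fewer macrophages in 1 culture each.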
